A study of Arabidopsis thaliana with 24 samples.

How the data were processed

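Whole seedlings of 4 lines (Col-0, MLB, EMS27 and rrc1-689) were sampled in darkness and in red light, with 3 libraries per group and 24 in all. Per the labels' protocols, seeds were kept cold for 2 days and given 6 h of white light at 50 µmol per m2 and s, then held for 60 h in darkness or in red light, and libraries were sequenced on an Illumina platform. The labels give 4 °C for the white light, the darkness and the red light alike, and whether seedlings grew at that temperature is unclear, which bears on the reading of cold, growth and seed genes. Groups and replicate numbers came from the sample titles. Reads were aligned with TopHat2 2.1.1 and the genome build was TAIR10, per the submitters' processing notes. The authors used ASpli 1.9 for both gene and splicing comparisons, per the information sheet deposited with the tables. Other settings, such as how strand and shared reads were counted, were not given in the sources used here.

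The authors deposited a table of log2 fold changes with a p-value and FDR per gene for each gene comparison, and listed genes with an absolute log2 fold change above 1 and an FDR below 0.01, per the information sheet. The scale and sign of the deposited log2 fold changes were checked against event reads of the same genes: 26 of 26 genes had the same sign, with a slope of 1.03. The tables held neither levels nor values per library, so no gene test was refitted and the authors' calls were counted. The number of genes tested was recovered from the relation FDR = p × N / rank, as 19143 for MLB over EMS27 and 19916 for red over dark. With these, 96.9% and 98.0% of listed genes had a whole rank within 0.01.

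For each splicing event the authors deposited raw read counts of the inclusion junctions or exon-intron boundaries and of the exclusion junction in each of 12 red-light libraries. They also deposited the fraction of inclusion (PSI) or intron retention (PIR) per group, from reads summed over replicates, with a p-value and FDR per bin. Events were listed by the authors where the fraction differed by more than 0.05 and the bin FDR was below 0.05, per the information sheet. The deposited fractions were recovered from the counts within 0.0001 for 324 of 325 and 328 of 328 events. The level per library was computed likewise, as inclusion reads over inclusion reads plus exclusion reads, the latter counted doubly where inclusion has 2 junctions. Levels are given as mean ± SD over 3 libraries. Limits for a count of 0 take 3 reads of the group's total, each read counted once. They cover counting error only, since reads without molecular identifiers are not independent molecules. Where the level counts exclusion reads doubly, such a limit is a share of reads and not a level.

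The main splicing test was limma 3.58.1 in R 4.3.3 on the logit of the level per library, with 0.5 added to both read sums and Benjamini-Hochberg adjustment over the listed events. Only the 2 groups compared entered each fit. The threshold was an adjusted p of 0.05. Differences between mutants in shared events came from an interaction contrast over 12 libraries. On simulated data with the real depths, the fit recovered 36.4% of events shifted by a logit of 1 and 81.1% of those shifted by 2 in the MLB and EMS27 comparison of 325 events, and called 4 of 125 unchanged ones. In the Col-0 and rrc1-689 comparison of 328 events it recovered 31.1% and 87.2%, and called 7 of 128. With 3 libraries against 3, a permutation test of a single event cannot go below p = 0.1. The median number of reads per event and library was 41 to 49 for MLB and EMS27 and 51 to 67 for Col-0 and rrc1-689, so differences in events of few reads were imprecise.

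Gene lists were fixed before the data were examined: 380 entries in 22 lists, covering the core clock, clock output, light signalling, PIF-induced growth, photosystems, chlorophyll synthesis, chloroplast regulators, auxin, gibberellin, brassinosteroid, ethylene, cell wall expansion, flavonoids, splicing factors, seed maturation, cold and dehydration, heat and defence, with markers of epidermis, stomata, root hairs and vasculature. A list with 5 or more members in a table was tested by a two-sided Fisher's exact test of direction against the other genes of that table. Adjustment ran over the 13 lists tested for red over dark and the 3 tested for MLB over EMS27. On simulated lists of 20 genes, 11 of 200 random ones had a p below 0.05. The genes named were the 8 largest rises and 8 largest falls, all listed core clock genes and, for each other list with 3 or more listed members, the 3 largest absolute changes. The events named were the 8 with the largest difference in fraction, lowest p first on ties, and every event in a core clock, light signalling or splicing factor gene. Events outside this rule, in VLN3, EX1 and TOM2A, were named after their values were seen.

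Gene names came from the TAIR10.1 annotation, with 11 and 44 identifiers of the MLB over EMS27 and red over dark comparisons without a name in it. Gene starts and ends were equal in the deposited tables and that annotation for 1134 of 1135 and 3841 of 3843 matched genes, and coordinates are those of the deposited tables. Of 266 intron events in each splicing comparison, 264 and 263 matched an annotated intron, and intron numbers count from the 5' end of an annotated transcript with that intron. Boundary reads of an intron were summed over the 3 libraries of the group with the higher level, for introns with at least 10 such reads, and read as lying at one boundary from 90% on and over both from 25% to 75% at the 3' boundary. This was chosen after seeing the data. Splice site scores were log2 odds from position weights over all annotated introns.

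The shared MLB red libraries were simulated 100 times with standard errors drawn from those of the listed genes, each from the deposited log2 fold change and p-value, and again with separate libraries. Genes that were not listed may have larger standard errors than these. Alternatives chosen before the data were examined were stricter thresholds, larger minimum differences, a minimum of 20 reads per group, leaving out each replicate and a replicate block. An offset of 1, edgeR 4.0.16's quasi-likelihood test on inclusion and exclusion counts, 1 event per gene, a minimum log2 fold change of 1.5 or 2 and an adjusted limma p in both comparisons were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Values of EMS27, Col-0 and rrc1-689 in darkness, and gene expression in Col-0 and rrc1-689, were not analysed here.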

Results

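RNA was sequenced from whole seedlings of Arabidopsis thaliana grown for 60 h in darkness or in red light of 19 µmol per m2 and s. The 24 libraries fell into 8 groups of 3, from 4 lines in each light condition. Col-0 is the wild type. MLB carries the red-light receptor phytochrome B (phyB) under the epidermal ML1 promoter in a phyB mutant, so that its phyB is made in the epidermis. EMS27 and rrc1-689 are rrc1 mutants, compared with MLB and Col-0, respectively. RRC1 is a splicing-related protein needed for phyB signalling. The labels did not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Gene-level results came from the authors' comparisons, without values per library. Splicing results came from junction reads in 12 red-light libraries, and values of the other 12 libraries were not used here, except MLB in darkness through the authors' comparison. Over the 325 events listed for MLB and EMS27, a library held 24482 to 28447 event reads, and over the 328 events listed for Col-0 and rrc1-689 it held 34004 to 38559. These sums cover listed events only and are not library depths. No row of RRC1 or PHYB was listed, so no value of either gene was analysed here.

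The first comparison asked which genes responded to red light in seedlings with phyB in the epidermis. Red light raised the photosynthesis genes of MLB together and lowered PIF-induced growth genes, ethylene genes, seed maturation genes and most listed auxin genes. The morning clock genes LHY and CCA1 rose 6.43-fold and 4.59-fold in the authors' deposited table. All 49 genes of the light-harvesting and photosystem list rose there, and the 10 listed PIF-induced growth genes all fell. The authors' deposited table held 3887 genes, 2540 higher in red light and 1347 higher in darkness, each with an absolute log2 fold change above 1 and an FDR below 0.01.

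The largest rises in the authors' deposited table were those of AT1G22690, a gibberellin-regulated family gene (log2 fold change 13.62, FDR 1.99e-260, chromosome 1, 8027126 to 8028168), and AT2G15020 (12.99, FDR 5.71e-232, chromosome 2, 6491425 to 6493512). The same authors' deposited table gave 11.59 for AT3G28270, 11.44 for the protein kinase gene CIPK20, 11.01 for the cytochrome P450 gene CYP71A22, 11 for LHCB1.4, 10.81 for the thionin gene AT1G66100 and 10.76 for AT3G11110. AT1G66100 overlaps another annotated locus. The largest falls in the authors' deposited table were those of CYP96A5 (-11.74, chromosome 2, 9341431 to 9343220) and BBX23, a B-box factor of light signalling (-11.69, chromosome 4, 6368829 to 6369950). Those of the protease inhibitor gene AT1G72290 (-11.43), the F-box gene AT1G20790 (-9.30), the copper transporter gene COPT3 (-8.25), the growth-regulating factor GRF7 (-7.64), PORA (-7.48) and the storage protein gene CRU3 (-7.24) followed in the authors' deposited table. Expression levels were not listed, so a ratio of this size can rest on few reads in the lower group.

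Among the 31 core clock genes, 11 rose, 1 fell and 19 had no row. The largest rises in the authors' deposited table were those of ASG4, also called REVEILLE 3 (3.3), LHY (2.68, FDR 3.27e-140, chromosome 1, 33365 to 37871), ELF4 (2.45), RVE1 (2.44), LNK2 (2.26) and CCA1 (2.2, FDR 5.62e-152, chromosome 2, 19245591 to 19248915). LHY and CCA1 are morning transcription factors, and ELF4 belongs to the evening complex. RVE8 (1.99), LNK1 (1.64), LNK3 (1.44), LNK4 (1.25) and RVE2 (1.02) rose too in the authors' deposited table, whereas the demethylase gene JMJ30 fell (-1.10). ASG4 and LNK4 each overlap another annotated locus. The share that rose was higher than that of the other listed genes (odds ratio 5.85), but without a call (two-sided Fisher's exact test, adjusted p = 0.111). With 12 listed genes the test had little power. Of the 10 clock output genes, 4 rose and 1 fell (adjusted p = 0.665), led by CDF1 (4.33), COL2 (3.04) and CDF3 (1.91) in the authors' deposited table.

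The 49 rises in the light-harvesting and photosystem list were more than the other listed genes gave (two-sided Fisher's exact test, adjusted p = 2.02e-08). The authors' deposited table gave 7.80 for LHCB1.2 and 7.45 for LHCB1.1, which encode light-harvesting proteins of photosystem II. LHCB1 and RBCS genes are near-identical copies that share reads, so the value of a single copy is uncertain. Of 19 chlorophyll synthesis genes 10 rose and 2 fell (adjusted p = 0.308), with CAO at 3.48, CHLH at 3.06 and PORA, the dark-grown protochlorophyllide reductase, at -7.48 in the authors' deposited table. All 7 listed chloroplast regulators rose (adjusted p = 0.150), and CGA1 (6.52), the sigma factor SIG5 (3.57) and GLK2 (2.26) led them in the authors' deposited table. Flavonoid genes numbered 7 that rose and 1 that fell (adjusted p = 0.326), and F3H (3.54), 4CL3 (2.65) and UGT78D2 (2.38) had the largest changes in the authors' deposited table.

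The 10 listed PIF-induced growth genes, targets of the phytochrome-interacting factors, all fell (two-sided Fisher's exact test, adjusted p = 0.000106), with XTH15 at -4.74, PIL1 at -4.45 and HFR1 at -2.93 in the authors' deposited table. Auxin genes fell in 17 cases and rose in 1 (adjusted p = 1.11e-06), with SAUR9 at -3.57 and SAUR10 at -3.24 against SAUR14 at 2.95 in the authors' deposited table. The 7 listed ethylene genes all fell (adjusted p = 0.00154), among them the ethylene synthesis genes ACS5 (-3.31) and ACS8 (-3.17) and the apical hook gene HLS1 (-3.19), as the authors' deposited table gave them. The 7 listed seed maturation genes all fell as well (adjusted p = 0.00154), with CRU3 at -7.24, CRU1 at -5.85 and SESA3 at -3.12 in the authors' deposited table. Cell wall expansion genes fell in 8 cases and rose in 4 (adjusted p = 0.0646), and XTH15 (-4.74), XTH30 (-2.16) and EXPA1 (2.12) moved most in the authors' deposited table. Gibberellin genes fell in 4 cases and rose in 1 (adjusted p = 0.0966), and GASA4 (-3.09), GASA6 (2.55) and the synthesis gene GA20OX1 (-2.27) moved most in the authors' deposited table.

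Light signalling genes went both ways, with 14 that rose and 11 that fell (adjusted p = 0.432), and after BBX23 the largest changes in the authors' deposited table were BBX25 at 5.58 and PIF7 at 4.43. Smaller groups were not tested because fewer than 5 members were listed. The 4 listed splicing factor genes fell, among them RS40 (-1.21), GRP8 (-1.15) and U2AF35B (-1.10) in the authors' deposited table. The brassinosteroid genes ROT3 (-1.17) and BAS1 (-1.16) fell and BES1 (1.13) rose in the authors' deposited table. Stomatal lineage markers rose in 3 of 3 listed cases, FAMA (2.1), SPCH (1.78) and TMM (1.12), and the root hair markers EXPA18 (2.21), EXPA7 (2.14) and COBL9 (2.01) were among 4 of 4 that rose in the authors' deposited table. Epidermis markers gave 1 rise and 1 fall. Vascular, cold and dehydration, and defence genes gave 1 rise each, and no heat gene was listed. Because rows of unlisted genes were not used here, counts adjusted over the list alone could not be had.

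The second comparison asked which genes differed in red light between MLB and its rrc1 mutant EMS27. In EMS27, the clock genes LHY, LNK2, RVE8, RVE1, ASG4 and CCA1 were lower and GI, PRR5 and FKF1 were higher. All listed auxin and seed maturation genes were higher in EMS27. LHY was 4.86-fold lower and GI 3.1-fold higher in EMS27 in the authors' deposited table. That table, the authors' deposited table for MLB over EMS27, held 1146 genes, 792 higher in MLB and 354 higher in EMS27.

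The genes highest in MLB over EMS27 in the authors' deposited table were AT3G16670, an extensin family gene (log2 fold change 7.58, FDR 4.03e-98, chromosome 3, 5681380 to 5682362), and CYP71A12 (7.15, FDR 1.83e-16, chromosome 2, 13099486 to 13101371). The noncoding gene AT2G05995 (4.78), AT2G15020 (4.37), AT2G34317 (4.29), AT4G12917 (4.02), the beta-glucosidase gene DIN2 (3.76) and MAM1, of glucosinolate synthesis (3.58), came next in the authors' deposited table. Genes highest in EMS27 in the authors' deposited table were AT3G15740, which encodes a RING protein (-5.99, chromosome 3, 5333769 to 5334553), the carboxypeptidase-like gene scpl44 (-5.12), NDB4 (-4.89) and AT1G64795 (-4.30). AT2G39415 (-3.91), AT1G09127 (-3.73), the late embryogenesis gene EM6 (-3.72) and AT3G23060 (-3.67) followed in the authors' deposited table.

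Of the 31 core clock genes, 6 were higher in MLB, 3 were higher in EMS27 and 22 had no row. The authors' deposited table gave log2 fold changes of MLB over EMS27 of 2.28 for LHY (FDR 2.48e-108), 2.06 for LNK2, 1.47 for RVE8, 1.41 for RVE1, 1.33 for ASG4 and 1.26 for CCA1 (FDR 3.96e-48). The evening-phased genes GI (-1.63, FDR 1.58e-62, chromosome 1, 8061751 to 8067790) and FKF1 (-1.07) and the pseudo-response regulator PRR5 (-1.03) were higher in EMS27 in the authors' deposited table. The share higher in MLB did not differ from that of the other listed genes, most of which were higher in MLB (two-sided Fisher's exact test, adjusted p = 1). Every library was taken at 60 h, so neither gene comparison shows how clock genes change over the day. A difference in level at that hour cannot be told apart from a difference in timing. Among clock output genes, COL2 (1.63) and COL1 (1.08) were higher in MLB and the RNA-binding protein gene GRP7 (-1.14) was higher in EMS27 in the authors' deposited table.

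**Figure D1:**
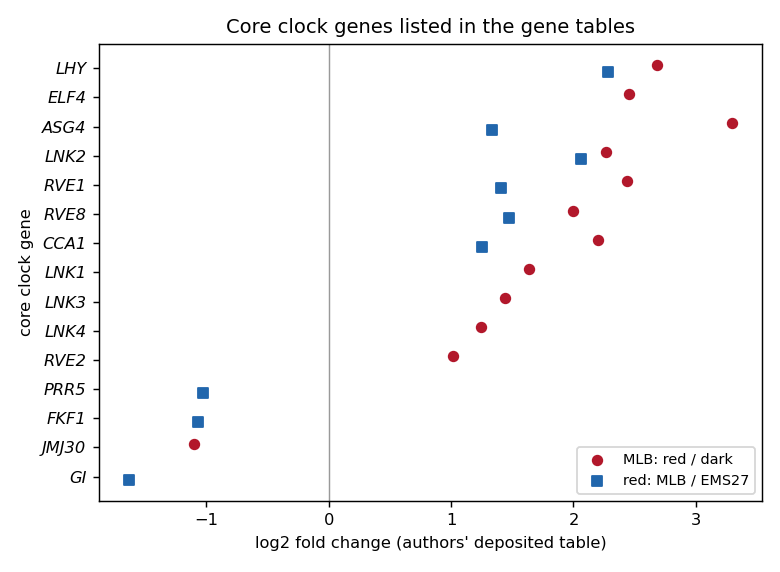
Log2 fold change on the horizontal axis for each listed core clock gene, with circles for MLB in red over darkness and squares for MLB over EMS27 in red light, both from the authors' deposited table. LHY, LNK2, RVE1, RVE8, CCA1 and ASG4 lie to the right of 0 in both comparisons, and a gene without a symbol of one kind had no row in that comparison.

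All 8 listed auxin genes were higher in EMS27 (two-sided Fisher's exact test, adjusted p = 0.000235), with IAA5 (-1.88), SAUR10 (-1.68) and IAA6 (-1.64) largest in the authors' deposited table. All 7 listed seed maturation genes were higher in EMS27 (adjusted p = 0.000386), with EM6 (-3.72), the oleosin gene OLEO1 (-3.41) and the storage protein gene CRU1 (-3.28) largest in the authors' deposited table. The other groups had fewer than 5 listed members and were not tested. Of the PIF-induced growth genes 4 were higher in EMS27, among them the sulfotransferase gene ST2A (-2.71), IAA19 (-1.39) and the auxin synthesis gene YUC8 (-1.35) in the authors' deposited table. IAA19 and YUC8 are also on the auxin list, so the counts of these lists overlap. The cold and dehydration genes COR15A (-2.92), RD29A (-1.74) and COR15B (-1.47) were higher in EMS27 in the authors' deposited table, as were 4 cell wall genes, led by XTH18 (-1.51), XTH17 (-1.06) and XTH19 (-1.05). COR15A and COR15B, and XTH18 and XTH19, are neighbouring copies that can share reads.

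The light signalling genes HYH (1.66), RUP2 (1.4) and BBX25 (1.25) were among 4 of 4 listed that were higher in MLB in the authors' deposited table. The 3 listed photosystem list members higher in MLB were the Rubisco small subunit genes RBCS2B (1.21), RBCS3B (1.08) and RBCS1B (1.05) in the authors' deposited table, which lie side by side on chromosome 5 and share reads. Flavonoid genes split, with 4CL3 (1.42) and the repressor MYBL2 (1.1) higher in MLB and the reductase DFR (-1.95) higher in EMS27 in the authors' deposited table. Listed members of the chlorophyll synthesis, gibberellin and ethylene lists were 2 each, all higher in EMS27, and 2 chloroplast regulators were higher in MLB. A splicing factor, GRP7, and 1 epidermis marker were higher in EMS27. No brassinosteroid, stomatal, root hair, vascular, heat or defence gene was listed. MAM1, PRR5 and RUP2 lie within 1 Mb of RRC1, in a region with more listed genes than most of the genome.

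The 2 gene comparisons were then set against each other. Of the 1146 genes listed for MLB over EMS27, 53.3% were also listed for red over dark, and 563 of these shared genes (92.1%) had the same direction. Thus 417 genes higher in red light were lower in the mutant, and 146 genes lower in red light were higher in the mutant. Another 38 genes were lower in red light and lower in the mutant, and 10 were higher in red light and higher in the mutant. The genes shared with the lists followed this pattern without exception, 43 list entries in all, including the 6 core clock genes LHY, CCA1, LNK2, RVE1, RVE8 and ASG4, 7 auxin genes and 5 seed maturation genes.

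Direction in one comparison went with direction in the other (two-sided Fisher's exact test, odds ratio 160, p = 8.79e-91). Independent lists of these sizes among 19143 genes tested would share 233 genes, 130 of them in the same direction. The number tested was recovered from the ratio of p-value to FDR, and the smaller of the 2 numbers was used. The MLB red libraries stood in both comparisons. In 100 simulations of unchanged groups sharing these libraries, the sign was the same for 66.7% of genes, against 50% with separate libraries. Hardly any simulated gene met both sets of criteria either way (means 0.6 and 0.02), so the simulations do not measure what the sharing adds among listed genes. The libraries could not be split, as no values per library were used, so part of the excess may come from the shared libraries.

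**Figure D2:**
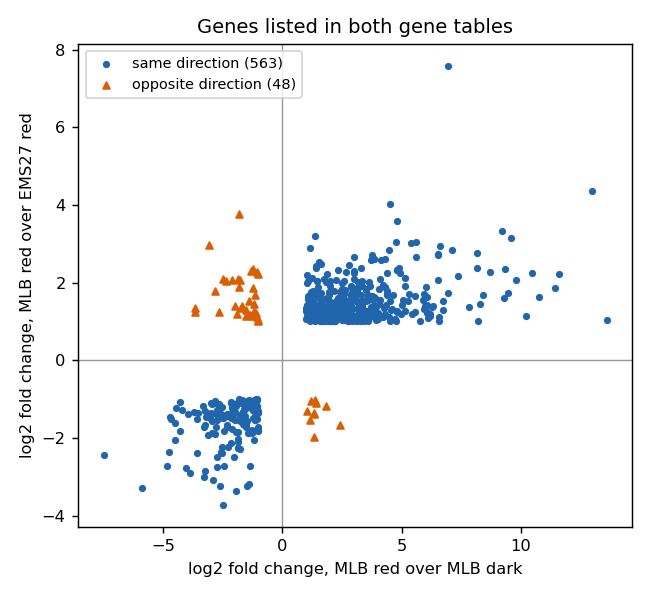
Each gene listed in both gene comparisons, with the log2 fold change of MLB in red over darkness on the horizontal axis and that of MLB over EMS27 in red light on the vertical axis, from the authors' deposited table. Circles mark the 563 genes with the same direction and triangles the 48 with opposite directions.

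The third comparison asked which splicing events differed between MLB and its rrc1 mutant EMS27. In EMS27, introns spliced in all annotated isoforms had a higher level than in MLB in most listed events. Among those with reads over both boundaries, however, 23 were higher and 40 were lower in EMS27. In most listed events, introns annotated as retained had a lower level and alternative 3' splice sites were included more often. Genes with changed events included the clock genes JMJ30 and TOC1 and the splicing factor gene U2AF65A. The included share of an alternative 3' splice site region of JMJ30 was 7.88% ± 1.5 (SD, n = 3) in MLB and 81.3% ± 3.75 in EMS27. The level of TOC1 intron 1 was 0.835% ± 0.724 in MLB and 7.19% ± 3.17 in EMS27. The authors' deposited table listed 325 events in 264 genes, of which 210 (64.6%) had a higher level in EMS27 and 115 a lower one (two-sided exact binomial test against equal shares, p = 1.52e-07, taking events as independent). In limma on the logit of the level per library, 291 of the 325 had an adjusted p below 0.05, 189 higher and 102 lower in EMS27. These events were listed by the authors from the same libraries, so the fit is not independent evidence.

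Kinds of event differed in direction. Alternative 3' splice sites were higher in EMS27 in 30 events and lower in 5 (Fisher's exact test against the other kinds, adjusted p = 0.0170). Introns annotated as retained in some isoform went the other way, higher in 11 and lower in 38 (adjusted p = 8.29e-10). Introns spliced in all isoforms were higher in 99 and lower in 48 (adjusted p = 0.413), and introns split by an annotated exon in 53 and 17 (adjusted p = 0.0793). Skipped exons numbered 10 higher and 2 lower (adjusted p = 0.394), alternative 5' splice sites 5 and 2 (adjusted p = 1), and unclassified exon parts 2 and 3 (adjusted p = 0.413).

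The level of an intron counts reads over its 2 boundaries, and a retained intron gives reads over both. Among introns with at least 10 boundary reads in the group with the higher level, 75 of the 145 that were higher in EMS27 (51.7%) had at least 90% of these reads at the 3' boundary, against 3 of 100 that were lower (Fisher's exact test, p = 3.95e-18). Reads lay over both boundaries, with 25% to 75% at the 3' one, in 36 and 74. A higher level of an intron is therefore not called retention below unless reads lay over both boundaries. This count was chosen after the data were seen.

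The largest difference was in AT1G69030, a BSD domain gene, at intron 2 (chromosome 1, 25948485 to 25948615, coding region). Its 181 MLB reads held 0 boundary reads, which allows up to 1.66% of reads. Its 87 EMS27 reads held 0 reads of the annotated junction, which allows up to 3.45% of reads. The logit difference has no upper limit on such reads, and limma's adjusted p was 7.86e-07. Levels did not vary between libraries (SD 0 in both groups), so this p rests on the 0.5 added and the read counts. Inclusion of the adjoining exon part (25948616 to 25948722) was 100% in MLB and 39.9% ± 13.8 (SD, n = 3) in EMS27. Loss of the annotated junction is therefore not called full retention of the intron. The JMJ30 alternative 3' splice site region (chromosome 3, 7277601 to 7277751) differed by a logit of 3.77 ± 0.27 (SE, limma adjusted p = 0.000118) over 117 and 154 reads. JMJ30 encodes a histone demethylase that takes part in the clock. The level of JMJ30 intron 4, which spans this region (7277452 to 7277751, coding region), rose from 13.5% ± 2.91 (SD, n = 3) to 60.6% ± 0.479 (limma adjusted p = 0.000733), but 85 of its 86 boundary reads in EMS27 lay at the 3' boundary, inside the alternative region, so the whole intron was hardly retained, and the annotated retained intron upstream of that site (7277452 to 7277600) fell from 45% ± 18 to 1.23% ± 0.321 (limma adjusted p = 0.000463), on 26 MLB reads.

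Intron 8 of the transporter gene AT1G67300 (chromosome 1, 25194779 to 25194892) was retained in 76.2% ± 31 (SD, n = 3) of MLB and 7.64% ± 1.23 of EMS27 (limma adjusted p = 0.00659). Intron 1 of EEL, a bZIP factor of seed maturation (chromosome 2, 17129776 to 17131239), went from 83.4% ± 15.5 to 17.7% ± 6.82 (limma adjusted p = 0.00461), with 38 of 39 boundary reads in MLB at the 5' boundary. Intron 7 of RIK (chromosome 3, 11291635 to 11291894) went from 92.5% ± 6.61 to 32.7% ± 8.71 (limma adjusted p = 0.00773). Inclusion rose for a 26-base exon of AT1G61150 (chromosome 1, 22542837 to 22542862), from 19.5% ± 15.2 to 86.1% ± 6.24 (limma adjusted p = 0.00426). It rose for a 15-base alternative 3' splice site region of AT1G19330 (chromosome 1, 6681501 to 6681515), from 31.1% ± 9.55 to 89.5% ± 13.0 (limma adjusted p = 0.00432).

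Splicing factor genes were among those changed. The retained intron of U2AF65A, which encodes a large subunit of the 3' splice site factor U2AF (chromosome 4, 17294604 to 17294703), fell from 20.9% ± 0.511 (SD, n = 3) to 1.32% ± 0.520 over 501 and 507 reads (limma logit -2.93 ± 0.29, SE, adjusted p = 0.000385). Intron 4 of AT1G60900, a gene of the same family (chromosome 1, 22425297 to 22425926), fell from 61.8% ± 2.81 to 26.2% ± 2.48 (limma adjusted p = 0.00215). Intron 6 of COP1, an E3 ligase of light signalling (chromosome 2, 13980525 to 13981051), rose from 2.71% ± 2.39 to 13.5% ± 4.13 (limma adjusted p = 0.0190), a call lost without EMS27 replicate 1 (adjusted p = 0.0567), with all 14 boundary reads in EMS27 at the 3' boundary. TOC1 intron 1 (chromosome 5, 24675673 to 24675989, coding region) differed by a logit of 1.87 ± 0.49 (SE, limma adjusted p = 0.0112) over 135 and 155 reads, with 18 of 20 boundary reads in EMS27 at the 3' boundary. Listed events in RVE8, GRP7 and RS40 did not pass limma. RVE8 intron 4 (chromosome 3, 2947404 to 2947521) stood at 14.6% ± 4.21 and 4.92% ± 4.33 (limma adjusted p = 0.0741), the GRP7 intron at 10% ± 1.48 and 15.5% ± 0.537 (limma adjusted p = 0.0830), and an RS40 exon part at 22.8% ± 9.18 and 11.3% ± 6.58 (limma adjusted p = 0.105). All 3 had an adjusted p below 0.05 in the edgeR quasi-likelihood test.

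The same question was asked of rrc1-689 against Col-0. Introns spliced in all isoforms again had a higher level in the mutant in most listed events, and alternative 3' splice site regions were included more often. Among such introns with reads over both boundaries, however, 27 were higher and 33 were lower in rrc1-689. JMJ30 inclusion of the alternative 3' splice site region was 13.0% ± 4.44 (SD, n = 3) in Col-0 and 81.9% ± 3.52 in rrc1-689, and the level of TOC1 intron 1 was 3.31% ± 1.91 and 12.9% ± 5.31. Events in SR34, SKIP, RS31, RS2Z32 and U2AF65A, all splicing factor genes, changed as well. The authors' deposited table listed 328 events in 270 genes, 236 (72.0%) higher and 92 lower in rrc1-689 (two-sided exact binomial test, p = 9.89e-16, taking events as independent). In limma 291 of the 328 had an adjusted p below 0.05, 208 higher and 83 lower in the mutant, with the same limit on independence.

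Introns annotated as retained were higher in 24 events and lower in 27, less often higher than the other kinds (Fisher's exact test, adjusted p = 0.000429). Alternative 3' splice sites were higher in 34 and lower in 5 (adjusted p = 0.0810, and 0.0162 with 1 event per gene). Introns spliced in all isoforms were higher in 108 and lower in 39 (adjusted p = 0.871), introns split by an annotated exon in 49 and 19 (adjusted p = 1), skipped exons in 13 and 2 (adjusted p = 0.437) and alternative 5' splice sites in 6 and 0 (adjusted p = 0.437). The 2 unclassified exon parts were higher (adjusted p = 1). Of the introns with at least 10 boundary reads, 82 of the 170 that were higher in rrc1-689 (48.2%) had at least 90% of these reads at the 3' boundary, against 4 of 80 that were lower (Fisher's exact test, p = 4.24e-13), and reads lay over both boundaries in 53 and 63.

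Intron 10 of AT5G24060, a pentatricopeptide repeat gene (chromosome 5, 8130378 to 8130482), had 0 boundary reads among 360 Col-0 reads, which allows up to 0.833% of reads. In rrc1-689 it had 0 reads of the annotated junction among 36, which allows up to 8.33% of reads. Limma gave an adjusted p of 8.19e-07 for the difference in level. Intron 1 of the cyclophilin gene AT3G55920 (chromosome 3, 20744878 to 20744968) went from 0 of 119 reads, which allows up to 2.52% of reads, to a level of 86.1% ± 10.7 (limma adjusted p = 7.94e-05). Intron 2 of the RNA export factor gene ALY4 (chromosome 5, 14982983 to 14983792) went from 14.3% ± 4.70 (SD, n = 3) to 100% of 165 reads (limma adjusted p = 1.40e-05). Neither this event nor that in AT5G24060 was listed for MLB and EMS27. As in EMS27, the level fell in AT1G67300 intron 8, from 90.5% ± 16.5 to 5.78% ± 3.82 (limma adjusted p = 0.00165), and in RIK intron 7, from 94.1% ± 5.95 to 25.2% ± 4.90 (limma adjusted p = 0.00290). UMAMIT40 intron 1, in the 5' UTR (chromosome 5, 16084898 to 16085023), went from 58.1% ± 42.9 to 0 of 28 reads (limma adjusted p = 0.00728). The AT3G07470 intron in the 3' UTR (chromosome 3, 2387345 to 2387521) went from 100% to 38.6% ± 18.3 (limma adjusted p = 0.00384). These last values rested on 20 and 8 Col-0 reads.

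In JMJ30 the alternative 3' splice site region differed by a logit of 3.41 ± 0.30 (SE, limma adjusted p = 0.000494) over 390 and 214 reads, and the level of the intron 4 spanning it rose from 12.1% ± 4.00 (SD, n = 3) to 62.4% ± 5.16 (limma adjusted p = 0.000886). In rrc1-689, 125 of its 128 boundary reads lay at the 3' boundary. TOC1 intron 1 differed by 1.43 ± 0.37 (SE, limma adjusted p = 0.0104) over 228 and 244 reads, with 52 of 55 boundary reads in rrc1-689 at the 3' boundary. PRR7 intron 4 (chromosome 5, 639994 to 640285) stood at 4.75% ± 5.73 in Col-0 and 12.5% ± 3.32 in rrc1-689 and did not pass (limma adjusted p = 0.0730), but did without Col-0 replicate 1 (adjusted p = 0.0122). Its boundary reads in rrc1-689 lay at the 3' boundary in 23 of 24 cases.

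In SKIP, which encodes a spliceosome component, inclusion of an alternative 3' splice site region (chromosome 1, 29001665 to 29001840) rose from 20.7% ± 5.84 (SD, n = 3) to 60.1% ± 13.3 (limma adjusted p = 0.00438), and the level of its 5' UTR intron 1 rose from 3.37% ± 4.39 to 14.4% ± 1.26 (limma adjusted p = 0.0221). Intron 2 of RS31 (chromosome 3, 22901256 to 22902053) rose from 6.71% ± 3.15 to 23.5% ± 6.12 (limma adjusted p = 0.00884), and intron 2 of RS2Z32 (chromosome 3, 19835756 to 19835872) fell from 12.2% ± 0.445 to 5.70% ± 0.976 (limma adjusted p = 0.0114). In U2AF65A the retained intron fell from 18.5% ± 3.44 to 2.72% ± 0.661 (limma adjusted p = 0.00105), and inclusion of the adjoining alternative 3' splice site region (chromosome 4, 17294431 to 17294603) rose from 62.0% ± 5.51 to 83.2% ± 2.94 (limma adjusted p = 0.00610). All 31 boundary reads of SKIP intron 1 and 111 of 115 of RS31 intron 2 in rrc1-689 lay at the 3' boundary. The U2AF65A intron spanning both regions stood at 46.6% ± 5.35 and 58.3% ± 3.08 and did not pass (limma adjusted p = 0.0852).

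SR34 had 4 listed events around its last introns. An 11-base alternative 3' splice site region (chromosome 1, 628935 to 628945) rose from 21.5% ± 3.64 (SD, n = 3) to 41.2% ± 0.292 (limma adjusted p = 0.00749), and the level of a long intron (628470 to 629287) rose from 7.75% ± 0.337 to 15.6% ± 1.08 (limma adjusted p = 0.0114). In rrc1-689, 129 of the 136 boundary reads of the long intron lay at the 3' boundary. A skipped exon (628777 to 628856) stood at 19.9% ± 6.20 and 32.4% ± 2.53 (limma adjusted p = 0.0486), and a 3' UTR intron (628857 to 628945) fell from 81.1% ± 20.1 to 37.6% ± 7.56 (limma adjusted p = 0.0267). The calls of the 3' UTR intron and of SKIP intron 1 were lost without any single rrc1-689 replicate, with adjusted p of 0.0520 to 0.0813 and 0.0525 to 0.0623. The skipped exon lost its call without Col-0 replicate 2 or 3 or any rrc1-689 replicate, with adjusted p of 0.0819 to 0.126, and in the replicate block (0.0921). SKIP intron 1 also lost its call without Col-0 replicate 1 (adjusted p = 0.0574). An SR34B retained intron (chromosome 4, 1070887 to 1071273) stood at 73.5% ± 26.8 and 34.6% ± 20.3 and did not pass (limma adjusted p = 0.0654), but did without Col-0 replicate 3 (adjusted p = 0.0242).

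**Figure D3:**
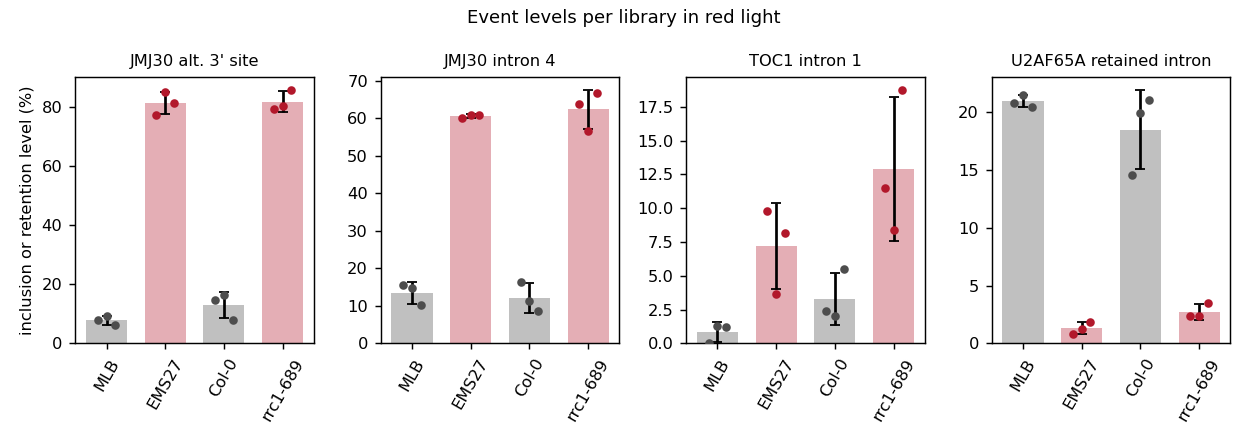
Inclusion or retention level in percent for 4 events in red light, with a bar for the group mean, an error bar of 1 SD and a point for each of 3 libraries. JMJ30 and TOC1 levels are higher in both rrc1 mutants than in their control lines, and the U2AF65A retained intron is lower in both.

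The last question was whether both mutants changed the same events. The comparisons share no library. Of the 325 and 328 events, 136 were identical in kind and position, in 112 genes, and all 136 had the same direction (two-sided exact binomial test against equal shares, p = 2.30e-41, taking events as independent). Equal shares understate agreement by chance, as 64.6% and 72.0% of listed events were higher in EMS27 and rrc1-689. Events of the same gene can also overlap, as those in JMJ30 do, so the p-value is too small. Direction was that of the pooled difference in the authors' deposited table, with 99 events higher and 37 lower in both mutants. Shared were the JMJ30 alternative 3' splice site and intron 4, TOC1 intron 1, the U2AF65A retained intron, RIK intron 7 and AT1G67300 intron 8. By kind, 51 were introns spliced in all isoforms (38 higher, 13 lower), 34 introns split by an annotated exon (27 and 7), 23 alternative 3' splice sites (21 and 2), 17 annotated retained introns (3 and 14), 8 skipped exons (7 and 1) and 3 alternative 5' splice sites (all higher). The gene sets of 264 and 270 had 115 genes in common.

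The median absolute difference of the shared events in the authors' deposited table was 0.165 for EMS27 and 0.137 for rrc1-689. It was larger in EMS27 in 83 of the 136 events (two-sided exact binomial test, p = 0.0126, taking events as independent, though they lay in 112 genes). Events of the MLB and EMS27 comparison had fewer reads, so larger differences may have been needed for listing there. Over all listed events the medians were 0.143 and 0.122. A stronger effect in EMS27 is therefore not claimed from these sizes. In limma over all 12 libraries, 3 events differed between the mutants in the size of the change at an adjusted p below 0.05, 1 each in VLN3, EX1 and TOM2A, and 13 at an unadjusted p below 0.05. With an offset of 1, chosen after seeing the data, TOM2A did not pass (adjusted p = 0.116). The other shared events, 1 in VLN3 (unadjusted p = 0.405) and 2 in EX1 (unadjusted p = 0.514 and 0.787), had no call.

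**Figure D4:**
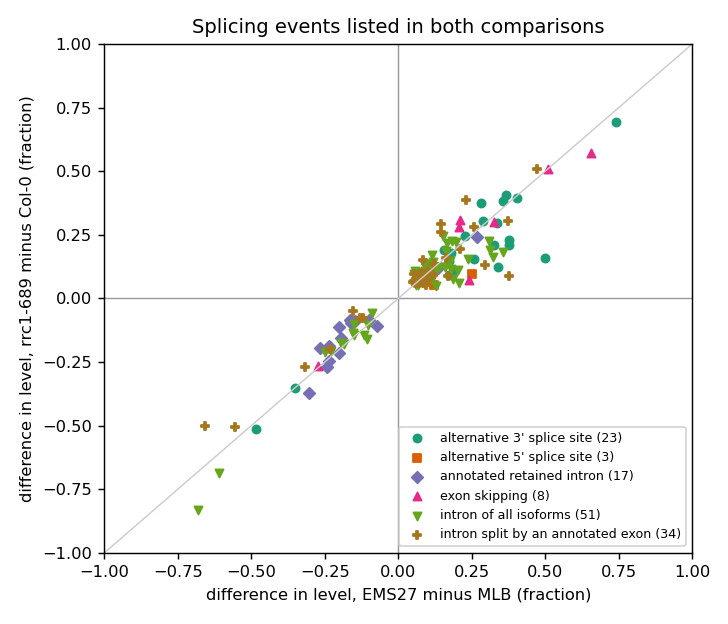
Difference in inclusion or retention level, as a fraction, for the 136 events listed in both comparisons, with EMS27 minus MLB on the horizontal axis, rrc1-689 minus Col-0 on the vertical axis and symbols for the kind of event. All 136 points lie in the upper right (99) or lower left (37) corner, and the grey diagonal marks equal differences.

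Events and expression were compared for MLB and EMS27. Of the 264 genes with listed events, 26 (9.85%) were also listed for expression, 20 higher in MLB and 6 higher in EMS27. Among all 19143 genes tested, 1146 were listed, 792 higher in MLB and 354 higher in EMS27. The clock gene RVE8, with a log2 fold change of 1.47 in the authors' deposited table, and GRP7, with -1.14, were among them, and neither event passed limma. Genes with a higher inclusion or retention level in EMS27 were lower in expression there in 12 cases and higher in 6, and the 8 genes with a lower level were all lower in expression. Since most listed genes were lower in EMS27, these counts do not link level with expression, and no test was run. JMJ30, TOC1 and U2AF65A had no row in the expression comparison of MLB and EMS27.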

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

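All tests in this part were chosen after the results were seen. Of the 136 events in both splicing comparisons, 3 were singled out because the change differed in size between the mutants by limma's interaction contrast, each larger in EMS27. In VLN3, which encodes a villin, the level of intron 20 (chromosome 3, 21244989 to 21245375) went from 3.34% ± 1.01 (SD, n = 3) to 42.1% ± 8.46 in EMS27 and from 6.38% ± 2.24 to 15% ± 1.68 in rrc1-689, with 297 of 298 and 130 of 131 boundary reads at the 3' boundary. The difference of the logit effects was 2.03 ± 0.39 (SE, limma adjusted p = 0.0307). In EX1, of chloroplast singlet oxygen signalling, intron 8 (chromosome 4, 16158339 to 16158622) went from 1.77% ± 0.756 to 22.1% ± 2.39 and from 3.33% ± 0.578 to 9.18% ± 1.16, a difference of effects of 1.59 ± 0.32 (SE, limma adjusted p = 0.0307), with 103 of 108 and 63 of 71 boundary reads at the 3' boundary. Retention of the whole intron is therefore not claimed for VLN3 or EX1. In TOM2A an alternative 3' splice site region (chromosome 1, 11690957 to 11691147) went from 0 of 296 reads, which allows up to 1.01%, to 18.1% ± 6.63, and from 2.54% ± 1.47 to 11.8% ± 5.51. With 0 MLB reads, the difference of effects of 2.27 ± 0.51 (SE, limma adjusted p = 0.0497) rests on the 0.5 added to the reads. With 1 added, an offset chosen after seeing the data, it was 1.77 ± 0.48 (SE, adjusted p = 0.116), so no difference in size is claimed for TOM2A. In VLN3 and EX1 the call held with 1 added (limma adjusted p = 0.0201 for each). Their other shared events had no call: an alternative 3' splice site in VLN3 (0.87 ± 1.00, SE, limma adjusted p = 0.946) and, in EX1, an intron split by an annotated exon (0.24 ± 0.36, SE, limma adjusted p = 0.977) and an alternative 5' splice site (0.09 ± 0.33, SE, limma adjusted p = 0.978). Line background and mutant allele differ together between the comparisons, and neither was tested apart.

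Whether the 291 events of either splicing comparison exceed what other groupings of the same libraries give was counted over the 10 splits of 3 against 3. The real split alone, 1 of 10, reached 291 events in each comparison, and the highest of the other splits gave 0. The events were chosen by the authors for differing in the real split of these libraries, so low counts in the other splits were fixed beforehand, and the splits are too few for a share under 0.05. The count therefore decides nothing.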

How the results depend on the processing

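An offset of 1, edgeR, 1 event per gene, limma calls in both comparisons and a minimum log2 fold change of 1.5 or 2 in lists and overlaps were chosen after seeing the data. A minimum absolute log2 fold change of 2 left 1380 genes for red over dark, 188 for MLB over EMS27 and 77 in both, 73 of these in the same direction. A minimum difference in fraction of 0.2 left 105 limma calls in EMS27, 85 in rrc1-689 and 36 shared events, and one of 0.1 left 179 in rrc1-689 and 86 shared. Other counts stayed within 1.5 times the reported ones. Leaving out each replicate gave 249 to 261 calls in EMS27, 250 to 281 in rrc1-689 and 111 to 120 shared events with calls in both, where all libraries gave 126. All events counted in these settings had the same direction in both mutants. Outside these counts, 1 shared event, in APX1, which did not pass limma in either comparison (adjusted p = 0.647 and 0.770), had a higher level in the mutants by pooled reads and a lower one by limma's mean over libraries, and it changed sign in 4 refits, those without MLB replicate 1 and without Col-0 replicate 2 and edgeR in both comparisons. The lists with a call numbered 7, and 8 at a minimum log2 fold change of 1.5. The ethylene list then had too few members to be tested, while cell wall expansion (adjusted p = 0.00651) and gibberellin (adjusted p = 0.0457) gained a call.

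The replicate numbers did not pair the libraries: deviations of same-numbered libraries did not correlate. With the replicate block, 276 and 284 events had calls and 119 shared events had calls in both. Over the 40 named events, 461 of 487 values kept their side of the threshold, 15 lost it, 11 gained it and 0 changed direction. The cause was not tested. For the gene comparisons, no paired analysis was possible because the tables hold no values per library. For the same reason the filters on low values, the pseudocount, DESeq2 and leaving out replicates were not run for genes. An FDR of 0.01 and an absolute log2 fold change of 1 are the authors' own criteria and changed nothing. Depth limits the events of few reads most.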

Other observations

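Most tests in this part were chosen after the results were seen, except the simulation of shared libraries and the red over dark count near RRC1, whose outcomes were predicted after the computation had run and before its output was read. Introns with a higher level in the mutants were long. In EMS27 their median length was 294 bases, against 128 for other introns of the same genes (145 genes, mean log2 difference 0.99 ± 0.08, SE, sign-flip permutation, adjusted p = 3.2e-05, from the smallest p that the permutations can give). In rrc1-689 the medians were 248 and 126 (171 genes, 0.80 ± 0.08, SE, adjusted p = 3.2e-05). There, introns with at least 90% of boundary reads at the 3' one had medians of 298 and 125 (82 genes, 1.18 ± 0.11, SE, permutation, adjusted p = 2.7e-05). Those with reads over both boundaries had medians of 104 and 134 (51 genes), so long introns in rrc1-689 were mainly those read at the 3' boundary. They also had a higher GC content than other introns, by 0.95 ± 0.34 (SE) percentage points in EMS27 (adjusted p = 0.00926) and 1.38 ± 0.25 in rrc1-689 (adjusted p = 3.2e-05). With reads over both boundaries this was 1.02 ± 1.11 (SE, permutation, adjusted p = 0.665) in EMS27 and 2.27 ± 0.45 (SE, adjusted p = 0.00016) in rrc1-689. Their 5' splice site score was higher by 0.81 ± 0.17 (SE) in rrc1-689 (adjusted p = 3.2e-05) and by 0.42 ± 0.21 in EMS27 (adjusted p = 0.0750). In introns with at least 90% of boundary reads at the 3' one it was higher by 1.34 ± 0.22 and 0.80 ± 0.24 (SE, permutation, adjusted p = 2.7e-05 and 0.00352). With reads over both boundaries the differences were 0.50 ± 0.32 and -0.35 ± 0.57 (SE, adjusted p = 0.367 and 0.669). A stronger 5' splice site is therefore not claimed for retained introns. Introns with a lower level in EMS27 were longer by a mean log2 difference of 0.31 ± 0.13 (SE, 95 genes, adjusted p = 0.0443), though their median was 122 against 132, and in rrc1-689 the difference was 0.04 ± 0.13 (SE, 74 genes, adjusted p = 0.818). They had a lower 3' splice site score than their neighbours, 6.73 against 8.73 on average in EMS27 (95 genes, permutation, adjusted p = 3.2e-05), and in rrc1-689 the means were 6.90 and 8.44 (74 genes, adjusted p = 0.004). Among introns spliced in all isoforms the means were 6.91 and 8.88 in EMS27 (46 genes, permutation, adjusted p = 0.00192). In rrc1-689 they were 7.34 and 8.06 (35 genes, adjusted p = 0.382), so the call was lost there.

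A larger bin collects more reads, so long introns may pass the authors' test more easily, which alone would lengthen introns in both directions alike. Within 4 classes of control level, introns that were higher in the mutant were longer than those that were lower by 0.84 in log2 in EMS27 (permutation, adjusted p = 0.00032). In rrc1-689 this was 0.74 (permutation, adjusted p = 0.0002, from the smallest p that 20000 permutations can give). Bin length alone would not give this at like control levels, but the classes may match levels only roughly. Median control levels of higher and lower introns were 2.33% and 24.3% in EMS27 and 3.44% and 20.8% in rrc1-689. Among introns with reads over both boundaries the differences were 0.57 and 0.48 (permutation, unadjusted p = 0.044 and 0.034, adjusted p = 0.0994 and 0.0920). These introns were fewer, 36 higher and 74 lower in EMS27 and 53 and 63 in rrc1-689. The lost call may reflect their number, and bin length stays open. A 3' splice site inside the intron, which a long intron has more room for, could also raise reads at the 3' boundary alone. Introns with reads over both boundaries that were higher were longer than other introns of the same genes by 0.70 ± 0.20 (SE, 35 genes, sign-flip permutation, adjusted p = 0.00588) in EMS27. In rrc1-689 they were longer by 0.12 ± 0.14 (SE, 51 genes, adjusted p = 0.665). Up to 75% of their boundary reads could still lie at the 3' boundary, and bin length could lengthen them too. These values therefore do not decide on such sites in either mutant. Within the same classes, the 3' splice site score of higher introns exceeded that of lower ones by 1.82 in EMS27 (permutation, adjusted p = 0.00907). In rrc1-689 this was 0.82 (permutation, adjusted p = 0.285). Among introns with reads over both boundaries these differences were no smaller, 2.11 and 1.47, but had no call on fewer introns (permutation, unadjusted p = 0.031 and 0.076, adjusted p = 0.0920 and 0.121). Low control level therefore stays open as an account of the score.

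The agreement in direction of the genes listed in both gene comparisons may come from the MLB red libraries they share. In 100 simulations of unchanged groups, at most 3 genes met both sets of criteria, and at most 1 with separate libraries, so the simulations decide nothing, and the shared libraries stay open without values per library. A weaker red-light response in EMS27 is a candidate explanation for the 92.1% with the same direction. It cannot be told apart from a difference between the lines that also exists in darkness, since EMS27 in darkness was not analysed here. Seed maturation genes, higher in EMS27 in 7 of 7 listed cases, leave a difference in the pace of germination open, which was not tested.

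Within 1 Mb of RRC1 (chromosome 5, 7636665 to 9636665), 29 of 454 coding genes (6.39%) were listed for MLB over EMS27, against 3.77% elsewhere. A share of 0.0447 of windows of as many consecutive genes held as many. For red over dark, 13.4% were listed in the window and 13.0% elsewhere, and a share of 0.449 of windows held as many. The window was thus not dense in genes that respond to red light. This does not test whether it is rich in genes prone to differ between MLB and EMS27, so gene content stays open. Sequence linked to the mutated gene may differ between the lines, but this stays open because no other rrc1 line had a gene comparison here. MAM1, PRR5 and RUP2 lie in this window.

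In 3 introns, all reads of the annotated junction were lost in one mutant while the control line had at least 30. None of these events was listed in the other comparison. AT1G69030 intron 2 had 181 such reads in MLB and 0 in EMS27. AT5G24060 intron 10 had 360 in Col-0 and ALY4 intron 2 had 217, and both had 0 in rrc1-689. AT5G24060 lies at 8130378 on chromosome 5, within 1 Mb of RRC1. Annotated retained introns were higher in 11 and lower in 38 events in EMS27 and in 24 and 27 in rrc1-689, a difference between the mutants that did not hold after adjustment over 7 kinds (Fisher's exact test, p = 0.0122, adjusted p = 0.0856).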
